A study of Mus musculus with 27 samples.

How the data were processed

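RNA was measured in mouse endothelial cells (EC), in mouse peritoneal macrophages (PMAC) and in the medium of endothelial cells. The 27 libraries formed 9 groups of 3. Polyadenylated RNA was sequenced from EC and PMAC libraries labelled chylomicron-treated, control or SRBI knockdown, and small RNA from endothelial cell media carrying the same 3 labels. SR-BI is the scavenger receptor class B type I, a lipoprotein receptor encoded by Scarb1. The labels stated no dose, time or cell line for a library, although the names of the chylomicron media libraries carry a number of unstated meaning. They did not say in which cells the knockdown was made for the macrophage and media libraries, nor whether knockdown libraries also received chylomicrons. They also left open whether macrophages labelled chylomicron-treated received chylomicrons or vesicles from treated endothelial cells. Group names below are therefore those of the labels.

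Per the labels, polyadenylated RNA libraries were prepared with a stranded mRNA kit and small RNA libraries with a multiplex small RNA kit. The submitters' processing notes named bcl2fastq, STAR 2.7.3a, featureCounts, Subread 1.6.3 and the builds mm10 and GRCm38, without a role for each. The deposited values of the 3 mRNA tables were a signal on the scale of normalized counts. Every nonzero value was a whole number of reads divided by a single factor per library, within a tolerance of 0.01 reads, so the whole reads could be recovered. The factors of the PMAC table equalled the DESeq2 median-of-ratios factors of its 9 columns. The factors of the EC table differed from those of its 6 columns by up to 1.19%. The 3 EC libraries with SRBI knockdown stood in a table of their own, without controls, and their factors lay 3.87% to 4.36% below those of the 3 columns. The deposited miRNA table held whole-number counts per mature miRNA, 35 of the entries under a joint name for 2 or more miRNAs, and neither the basis of merging nor the counting step was stated.

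Recovered reads assigned to genes ranged from 40046820 to 46700757 per library in the table of EC chylomicron and control, from 30547284 to 55874954 in the PMAC table and from 16758727 to 20715157 in the EC SRBI knockdown table. The miRNA libraries held 750534 to 2786583 counts. Among the 27 pairs of replicates none held identical values. Sequencing reads without molecular identifiers are not independent molecules, so the precision stated here covers the spread between libraries. Only the spread between 3 libraries per group was available to each test.

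For the mRNA tables, log2 of the normalized count plus 1 was fitted with limma 3.58.1 in R 4.3.3 with the group as the term (empirical Bayes with a trend, two-sided tests), in genes with a mean of at least 10. The 3 PMAC groups shared a single fit of 9 libraries, and the EC fit used 6. For miRNA, the edgeR 4.0.16 quasi-likelihood test with TMM scaling was fitted to the 9 libraries in miRNAs with a mean count of at least 5. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The EC libraries with SRBI knockdown were not tested against the other EC libraries, since the design written before the data were examined left tables scaled separately untested against each other, and this was kept although the reads could be recovered. Each adjusted p below is from limma for genes and from edgeR for miRNAs, each with n = 3 libraries per group. Gene positions are those of the RefSeq annotation of GRCm38.

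Gene lists of pathways and cell types were written before the data were examined, 38 for genes and 14 for miRNAs, of which 9 and 5 were markers of cells that a sample could hold besides the labelled cell. A list was tested when at least 5 members were measured. The number of members past the threshold was counted over all genes tested and adjusted over the list alone. The lists of a comparison were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of the comparison. Named genes followed a rule also written before the data were examined. It took Scarb1, the 6 genes with the highest and the 6 with the lowest change among those past the threshold with a mean of at least 100 and no overlap between the groups (4 in each direction for SRBI knockdown against chylomicron), and up to 4 members of each list past the threshold by smallest p. Predicted gene models were left out, and 1 gene that the rule took is not reported here. For miRNAs it took the same numbers at a mean of at least 10 CPM, the 5 most abundant, the same share of each list, and up to 3 in a direction by smallest p where too few passed. Genes outside the rule are identified where they appear. In every gene or miRNA named as having risen or fallen, the 3 libraries of 1 group lay outside the range of the 3 libraries of the other. Counts of list members that rose or fell rest on the threshold and the direction alone.

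On data simulated in a single run per table, with the spread taken from its trend with abundance, the EC procedure called 77.8% of genes changed by 1 on the log2 scale and 93.9% of those changed by 2. The PMAC procedure called 69.7% and 90.8%, and the miRNA procedure 5.56% (1 of 18) and 60.0% (12 of 20). Few genes were changed in these runs, so the rates need not hold for the real comparisons. False calls made up 3.95%, 5.39% and 0% of the calls.

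Alternatives set before the data were examined were other pseudocounts, filters and scalings, empirical Bayes without a trend, sample weights, a term for the replicate number, the 6 compared libraries alone, and each library left out in turn. For miRNA they also included DESeq2 1.42.0, voom and leaving out the most abundant miRNA. Chosen after seeing the data were edgeR and DESeq2 on the recovered reads, leaving out libraries that stood apart, thinning all PMAC libraries to the reads of the shallowest, and applying the alternatives to the overlap of the PMAC comparisons. Lists with fewer than 5 measured members in a table were not tested there.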

Results

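The data covered endothelial cells, peritoneal macrophages and endothelial cell media from mice, in groups of 3 libraries. The series title names extracellular vesicles from chylomicron-treated endothelial cells and macrophage inflammation. Chylomicrons are the large lipoproteins that carry dietary fat from the intestine. The EC chylomicron libraries held 41903092 to 45457472 reads assigned to genes and the EC control libraries 40046820 to 46700757. The PMAC chylomicron libraries held 30547284 to 38394674, the PMAC control libraries 42775013 to 45991856 and the PMAC SRBI knockdown libraries 38332909 to 55874954. The media libraries held 750534 to 2114357 miRNA counts under chylomicron, 1625709 to 2761105 under control and 2180292 to 2786583 under SRBI knockdown.

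In endothelial cells, some acute-phase and chemokine transcripts were far more abundant after chylomicron treatment than in controls. Acute-phase genes were not tested as a list. Saa3, which encodes an acute-phase serum amyloid A protein (chromosome 7, 46711998 to 46719615), averaged 4355 ± 1225 normalized counts (SD, n = 3) with chylomicrons and 28.4 ± 7.64 in controls, a log2 fold change of 7.20. Lcn2, the iron-sequestering protein lipocalin 2, rose by 5.76 on the log2 scale (adjusted p = 3.54e-11), and Steap4, a metalloreductase, rose by 4.51 (adjusted p = 1.06e-11). The monocyte-attracting chemokine gene Ccl2 (chromosome 11, 82035577 to 82037452) rose from 1015 ± 44.9 to 16713 ± 3813 normalized counts, and Cxcl5 and Ccl7 rose by 4.44 and 4.13. Among the genes with the lowest changes were Aqp8 (log2 fold change -2.09), an aquaporin, Fmo2 (-2.02), a flavin monooxygenase, and Angpt2 (-1.92), an angiopoietin that endothelial cells secrete. Gkn3 (-1.74) and Slc25a34 (-1.72) also fell.

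**Figure D1:**
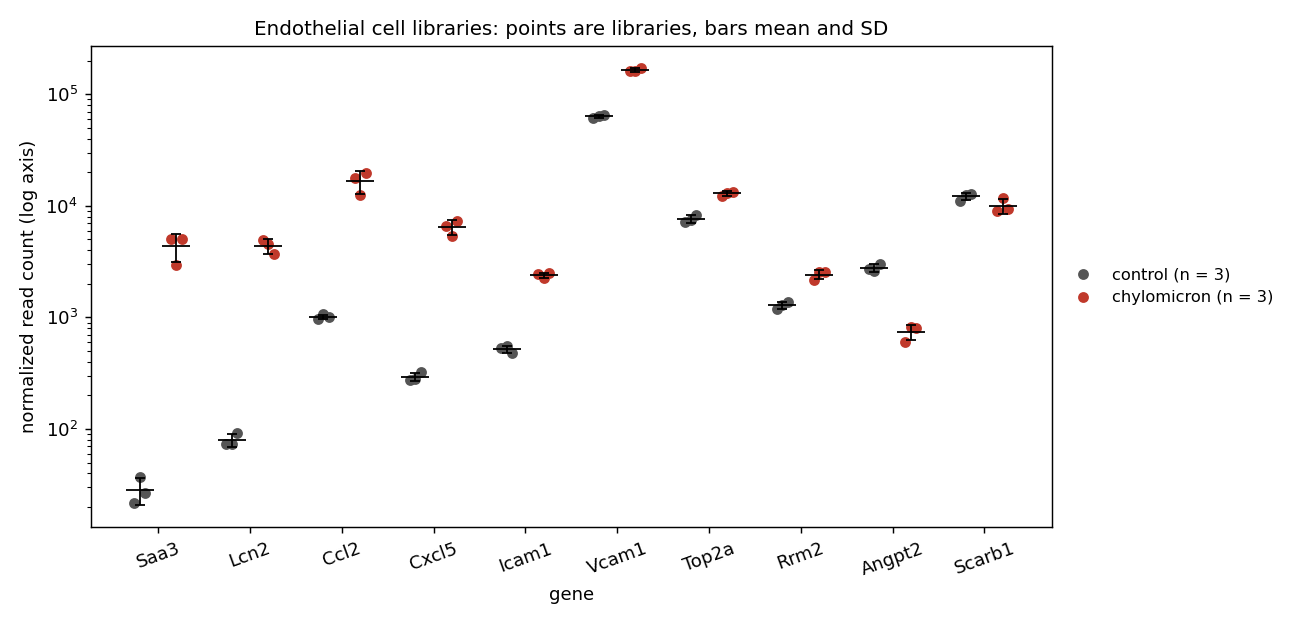
Normalized read counts (log axis) of 10 named genes in the 3 control and 3 chylomicron endothelial libraries, with a point per library and bars for the mean and SD. Saa3, Lcn2, Ccl2, Cxcl5, Icam1, Vcam1, Top2a and Rrm2 lay above control in every chylomicron library, Angpt2 lay below, and the Scarb1 libraries overlapped.

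Of 32 measured members of the list of NF-kB and inflammatory cytokine genes, 23 rose and 1 fell in endothelial cells (26 and 1 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.00597). Tlr2, a receptor for bacterial lipoproteins, rose by 2.43 on the log2 scale. The single member that fell was Il1a, at -1.56 (adjusted p = 0.0128), a gene named after its values were seen. Its call was lost without EC control replicate 1 (adjusted p = 0.0837) and with empirical Bayes without a trend (adjusted p = 0.108), over a range of 3.23e-04 to 0.108. Of 15 chemokine and leukocyte recruitment genes, 10 rose and 0 fell by limma (11 and 1 adjusted over the list alone), and this call also held with an estimated correlation (adjusted p = 0.0305). Cxcl1 rose by 2.84. In the endothelial adhesion and activation list, 7 of 18 members rose and 2 fell (7 and 3 adjusted over the list alone), with an adjusted p of 0.308 with an estimated correlation. Leukocyte adhesion receptors were among those that rose, with Sele at 2.36, Icam1 at 2.20 and Vcam1 at 1.39.

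Of 38 cell cycle genes measured in endothelial cells, 37 rose and 0 fell by limma (38 and 0 adjusted over the list alone), with a median log2 fold change of 0.66. With empirical Bayes without a trend 22 rose, and the adjusted p of the list was 0.164 with an estimated correlation. Examples were Rrm2 (0.91), a ribonucleotide reductase subunit, Uhrf1 (0.83), Top2a (0.77) and the mitotic kinesin gene Kif11 (0.75). In the list of type II interferon and antigen presentation genes, 11 of 25 members rose and 0 fell (16 and 0 adjusted over the list alone), among them the guanylate-binding protein genes Gbp5 (1.67) and Gbp2 (0.94). Its adjusted p was 0.220 with an estimated correlation. Of 29 immediate early genes 10 rose and 0 fell (16 and 0 adjusted over the list alone), including Ier3 (1.18), Junb (1.07) and Zfp36 (0.85). Of 25 genes of cholesterol biosynthesis and SREBP2 targets 7 rose and 0 fell (15 and 1 adjusted over the list alone), including Sqle (0.53). With an estimated correlation the adjusted p was 0.387 for both lists. Without EC control replicate 1, 6 immediate early genes and 2 cholesterol genes rose, and without EC control replicate 2, 3 cholesterol genes did. With empirical Bayes without a trend, 7 type II interferon, 5 immediate early and 1 of the cholesterol genes rose.

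Genes of lipid handling moved in both directions in endothelial cells. In the list of lipid uptake and lipoprotein receptors 4 of 19 members rose and 1 fell (4 and 2 adjusted over the list alone), with Lrp8 at 0.74, Acsl5 at 0.62 and Vldlr at 0.54, and camera gave an adjusted p of 0.160. Among 14 LXR targets 2 rose and 2 fell (2 and 4 adjusted over the list alone). The LXR gene Nr1h3 rose by 0.96 and Arl4c by 0.87, and camera gave an adjusted p of 0.460. Of 25 genes of PPAR-responsive fatty acid oxidation 0 rose and 4 fell (0 and 5 adjusted over the list alone), including Ucp2 (-0.62), with an adjusted p of 0.387 with an estimated correlation. Without EC chylomicron replicate 1 or EC control replicate 3, 2 of these fell. Among 36 genes of extracellular vesicle biogenesis and markers, 3 rose and 1 fell (4 and 1 adjusted over the list alone), the tetraspanin gene Cd82 rose by 0.82, and 1 member rose without EC control replicate 1 or 2. Of 26 endothelial identity genes 0 rose and 5 fell (1 and 7 adjusted over the list alone), including Egfl7 (-0.50), whose adjusted p was 0.0541 with empirical Bayes without a trend, over a range of 3.74e-07 to 0.0541. The adjusted p of that list was 0.427 with an estimated correlation. The number that fell was 2 without EC control replicate 1 or 2, 3 without EC chylomicron replicate 1 or 3, and 8 without EC chylomicron replicate 2.

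Markers of other cells did not rise as groups in the endothelial libraries. Of 12 macrophage identity genes 1 rose and 1 fell, of 16 fibroblast and mural cell genes 0 rose and 3 fell, of 11 mesothelial genes 0 passed, and of 6 erythroid and platelet genes 1 rose and 2 fell. The gene that rose in the last of these was Pf4, platelet factor 4, at 1.07. Chylomicron replicate 2 stood apart from the other 5 libraries on the first principal component, at -74.5 where the others ranged from -4.91 to 30.9. In control replicate 1 the mitochondrial transcript mt-Co1 took 3.47% of reads, and in chylomicron replicate 1 CT010467.1 took 2.13%.

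Over all genes, 1317 of 15595 passed the threshold in endothelial cells, of which 805 were higher and 512 lower with chylomicrons, and 3845 genes (24.7%) had no overlap between groups where chance gives 10%. Without EC control replicate 1 the count was 744 and without EC control replicate 2 it was 803. It was 587 with empirical Bayes without a trend. Scarb1 (chromosome 5, 125277087 to 125341094), the gene of SR-BI, averaged 9988 ± 1519 normalized counts (SD, n = 3) with chylomicrons and 12144 ± 919 in controls, and its log2 fold change of -0.29 did not pass the test (adjusted p = 0.147). It passed without EC chylomicron replicate 2 (log2 fold change -0.41, adjusted p = 0.0107), with sample weights, and with EC chylomicron replicate 2 and EC control replicate 1 both left out. Its adjusted p ranged from 0.00930 to 0.408 over the alternatives.

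The endothelial libraries labelled SRBI knockdown came without controls in their table and with 16758727 to 20715157 reads, so their values were set beside the other endothelial libraries as RPM (reads scaled to equal library totals) without a test. Scarb1 averaged 117 ± 3.14 RPM (SD, n = 3) in them, 281 ± 26.7 in EC control and 235 ± 34.8 in EC chylomicron. In a count chosen only after the data were seen, 23 of 26 endothelial identity genes were lower in every one of these libraries than in any EC control and 1, Lyve1, was higher. Cdh5 was at 46.2 ± 3.19 against 363 ± 35.1 in EC control and Pecam1 at 73.9 ± 1.37 against 175 ± 11.6. Differences were not confined to that list, with the matrix genes Col3a1 at 6087 ± 1083 against 15788 ± 1216 and Fn1 at 4303 ± 444 against 16248 ± 2372, Gapdh at 1067 ± 15.8 against 468 ± 32.9, and CT010467.1 at 13672 ± 256 against 4441 ± 1981. Saa3 averaged 1067 ± 26.1 RPM there, against 103 ± 29.5 in EC chylomicron and 0.659 ± 0.183 in EC control. Ccl2 averaged 256 ± 30.1 RPM there, between EC control (23.5 ± 1.36) and EC chylomicron (394 ± 94.4). No control shared the table of the knockdown libraries. Effects of the knockdown, also on Scarb1, therefore cannot be told apart from other differences between these sets of libraries.

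In peritoneal macrophages, the libraries labelled chylomicron-treated held many times more cytokine transcript than the controls. Il1b, the gene of interleukin-1 beta (chromosome 2, 129364569 to 129371164), averaged 417253 ± 3225 normalized counts (SD, n = 3) against 12739 ± 2649, a log2 fold change of 5.06 (adjusted p = 2.71e-16). Il6 averaged 35463 ± 1697 against 351.8 ± 100, a log2 fold change of 6.69. Among genes with a mean of at least 100 and no overlap between the groups, the highest changes besides Il6 were those of the long noncoding RNA gene U90926 (7.40), Inhba (7.01), which encodes an activin subunit, the growth factor gene Csf2 (6.95), Ifitm1 (6.87) and Hdc (6.40), the histamine-forming enzyme. The lowest were those of Hal (-3.70), the B cell chemokine gene Cxcl13 (-3.18), the sialyltransferase genes St8sia6 and St6gal1 (-3.06 each), Timd4 (-3.01), a receptor for apoptotic cells on resident macrophages, and Nav2 (-2.96).

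**Figure D2:**
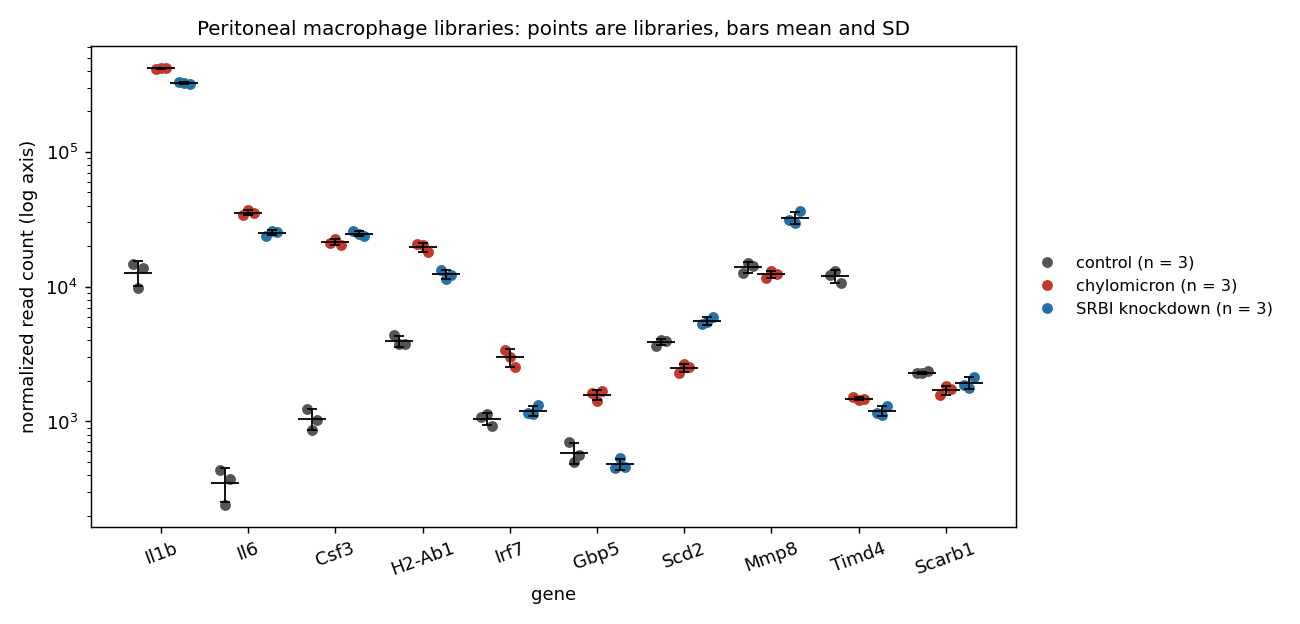
Normalized read counts (log axis) of 10 named genes in the 9 macrophage libraries, with a point per library and bars for the mean and SD of each group of 3. Il1b, Il6, Csf3 and H2-Ab1 lay above control and Timd4 below control in both other groups, while Irf7 and Gbp5 lay lower and Scd2 and Mmp8 higher in SRBI knockdown than in chylomicron libraries.

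Of 41 NF-kB and inflammatory cytokine genes, 34 rose and 2 fell in chylomicron macrophages (34 and 2 adjusted over the list alone), including Csf3 (4.37), Il1a (3.47) and Cxcl5 (3.65). The adjusted p of the list was 0.0756 with an estimated correlation. Of 21 chemokine and leukocyte recruitment genes, 11 rose and 5 fell (11 and 7 adjusted over the list alone), with Cxcl1 at 3.45, Ccl5 at 3.03 and Cxcl2 at 2.55, and the adjusted p was 0.106 with an estimated correlation. In 2 interferon-related lists more genes rose than fell, and the adjusted p of both was 0.242 with an estimated correlation. Of 29 type I interferon response genes 17 rose and 3 fell (18 and 3 adjusted over the list alone), including Oasl1 (1.83) and Zbp1 (1.38). Of 29 type II interferon and antigen presentation genes 18 rose and 6 fell (20 and 6 adjusted over the list alone), including Socs1 (3.32) and the major histocompatibility genes H2-Ab1 (2.31) and H2-D1 (0.61).

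Secretory stress transcripts also rose in chylomicron macrophages. Of 23 genes of the unfolded protein response of the endoplasmic reticulum 16 rose and 1 fell (17 and 1 adjusted over the list alone), such as Creld2 (0.83), Pdia4 (0.82), Manf (0.61) and the chaperone gene Hspa5 (0.51), with an adjusted p of 0.159 with an estimated correlation. Of 24 targets of the integrated stress response 12 rose and 2 fell (12 and 2 adjusted over the list alone), including Ddit4 (1.94) and Atf3 (0.66), with an adjusted p of 0.113 with an estimated correlation. Among 27 immediate early genes 15 rose and 5 fell (16 and 5 adjusted over the list alone), with Dusp1 at 1.57, Socs3 at 1.45 and Ier3 at 1.44. That list had an adjusted p of 0.159 with an estimated correlation.

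More genes of fatty acid synthesis and oxidation fell than rose in chylomicron macrophages, though neither list passed with an estimated correlation, while other lipid genes went both ways. Of 15 fatty acid synthesis genes 0 rose and 10 fell (0 and 10 adjusted over the list alone), among them the lipogenic transcription factor gene Mlxipl (-1.88), the desaturase genes Fads1 (-1.21) and Scd2 (-0.64), and Acss2 (-1.11), and the adjusted p of the list was 0.0756 with an estimated correlation. Of 25 genes of PPAR-responsive fatty acid oxidation 0 rose and 14 fell (0 and 15 adjusted over the list alone), including Angptl4 (-1.54), Ucp2 (-0.73) and Cpt1a (-0.48), with an adjusted p of 0.159 with an estimated correlation. The lysosomal acid lipase gene Lipa fell by 1.18 on the log2 scale. Cholesterol exporters went the other way, with Abca1 at 0.94 and Abcg1 at 0.61, within a list of LXR targets of which 3 of 14 rose and 6 fell (3 and 7 adjusted over the list alone) and for which camera gave an adjusted p of 0.505. The lipid droplet gene Hilpda rose by 1.84. In the list of lipid uptake and lipoprotein receptors 7 of 22 members rose and 9 fell (7 and 9 adjusted over the list alone), and camera gave an adjusted p of 0.590. Of 24 genes of cholesterol biosynthesis and SREBP2 targets 4 rose and 1 fell (3 and 1 adjusted over the list alone), with a camera adjusted p of 0.505, and 2 rose without PMAC chylomicron replicate 2 and 1 without PMAC control replicate 2.

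Macrophage identity genes shifted mostly downward. Of 23 members 5 rose and 14 fell (5 and 14 adjusted over the list alone), with Aif1 at -2.43, the mannose receptor gene Mrc1 at -1.97 and Trem2 at -1.48 against the lipopolysaccharide co-receptor gene Cd14 at 1.64, and the adjusted p was 0.573 with an estimated correlation. The scavenger receptor gene Marco fell by 0.98. In the list of alternative macrophage activation 6 of 15 members rose and 2 fell (7 and 2 adjusted over the list alone), with Ccl22 at 5.88, and camera gave an adjusted p of 0.0922. Of markers of other cells, 3 of 5 neutrophil genes rose and 1 fell, 4 of 9 dendritic cell and monocyte genes rose and 3 fell, 1 of 5 B cell genes rose and 2 fell, 1 of 8 mast cell and eosinophil genes (Hdc) rose and 0 fell, 0 of 9 mesothelial genes rose and 2 fell, and 2 of 11 fibroblast and mural cell genes rose and 6 fell.

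In total 4550 of 13630 genes passed the threshold between chylomicron and control macrophages, 2178 higher and 2372 lower, and 5792 genes (42.5%) had no overlap between groups where chance gives 10%. Scarb1 averaged 1713 ± 132 normalized counts (SD, n = 3) against 2308 ± 40.6, a log2 fold change of -0.43 (adjusted p = 1.98e-04). Chylomicron replicates 1 and 2 were the shallowest macrophage libraries, with 30733117 and 30547284 reads. With both left out, 3257 genes passed.

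Macrophages labelled SRBI knockdown also differed widely from the same controls. U90926 rose by 7.23 on the log2 scale, the stefin gene Cstdc4 by 6.88, Csf2 by 6.79, Ifitm1 by 6.36, the activin antagonist gene Fst by 6.29 and Il6 by 6.20. Il1b averaged 323289 ± 6241 normalized counts (SD, n = 3) against 12739 ± 2649, a log2 fold change of 4.69 (adjusted p = 8.19e-16). The lowest changes among genes with a mean of at least 100 were those of Cxcl13 (-3.78), Hal (-3.34), the semaphorin gene Sema4d (-3.33), Timd4 (-3.32), Cyfip2 (-3.25) and St8sia6 (-3.20). A knockdown was not clear in the Scarb1 transcript of these macrophages, and the labels do not say in which cells it was made. Scarb1 averaged 1932 ± 196 normalized counts against 2308 ± 40.6 in controls, a log2 fold change of -0.26 (adjusted p = 0.0127, 95% interval -0.42 to -0.10). That call was lost without PMAC SRBI knockdown replicate 1 (adjusted p = 0.0559), without PMAC SRBI knockdown replicate 2 (adjusted p = 0.0812) and with empirical Bayes without a trend (adjusted p = 0.0672), over a range of 0.00233 to 0.0812.

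Of 41 NF-kB and inflammatory cytokine genes 31 rose and 5 fell in SRBI knockdown macrophages (31 and 5 adjusted over the list alone), with Csf3 at 4.58 and Il1a at 3.34, and Icam1 at -0.64 among those that fell. The adjusted p was 0.107 with an estimated correlation. Of 21 chemokine and leukocyte recruitment genes 13 rose and 4 fell (13 and 4 adjusted over the list alone), with Cxcl1 at 3.09, Cxcl3 at 2.93 and Cxcl2 at 2.29, and an adjusted p of 0.0845 with an estimated correlation. Of 27 immediate early genes 16 rose and 3 fell (16 and 3 adjusted over the list alone), including Socs3 (1.51), Ier3 (1.36) and Fosl1 (0.76), with an adjusted p of 0.107 with an estimated correlation. Neither interferon list was called by camera against control, though more type I members fell than rose. Of 29 type I interferon response genes 2 rose and 11 fell (2 and 11 adjusted over the list alone), with Mx1 at -2.38, Rsad2 at -1.48, Oas2 at 0.61 and Zbp1 at 0.56, and camera gave an adjusted p of 0.174. Of 29 type II interferon and antigen presentation genes 5 rose and 7 fell (5 and 7 adjusted over the list alone), with H2-Ab1 at 1.65, Gbp7 at 0.74 and Gbp2 at -0.54, and camera gave an adjusted p of 0.553. With quantile normalization 12 members of the latter list fell, and 3 rose without PMAC control replicate 2 or 3 or without PMAC SRBI knockdown replicate 1 or 3. Of the type I genes 4 rose without PMAC SRBI knockdown replicate 2.

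In 4 lists of energy metabolism, oxidative stress and degradation more genes fell than rose in SRBI knockdown macrophages against control, and none of the 4 passed with an estimated correlation. Of 34 nuclear-encoded oxidative phosphorylation genes 0 rose and 19 fell (0 and 23 adjusted over the list alone), by small amounts such as Sdha (-0.36) and Atp5a1 (-0.29), with an adjusted p of 0.558 with an estimated correlation. Of 25 genes of PPAR-responsive fatty acid oxidation 0 rose and 14 fell (0 and 15 adjusted over the list alone), including the fatty acid-binding protein genes Fabp3 (-2.01) and Fabp4 (-1.26), with an adjusted p of 0.107 with an estimated correlation. Of 25 NRF2 oxidative stress targets 3 rose and 14 fell (5 and 14 adjusted over the list alone), including Taldo1 (-0.62) and the catalase gene Cat (-0.56), with an adjusted p of 0.277 with an estimated correlation. Of 38 lysosome and autophagy genes 7 rose and 18 fell (7 and 18 adjusted over the list alone), including Lipa (-1.32) and Psap (-0.60), with an adjusted p of 0.599 with an estimated correlation, and 4 rose without PMAC control replicate 3 or PMAC SRBI knockdown replicate 1 or 3. Fatty acid synthesis genes were mixed, with 2 of 15 higher (Scd2, 0.52) and 3 lower (Acss2, -1.19, and Fads1, -0.65), and camera gave an adjusted p of 0.391. Abca1 rose by 1.24 and Abcg1 by 0.83. Of 23 macrophage identity genes 3 rose and 15 fell (3 and 15 adjusted over the list alone), with Aif1 at -2.69, Trem2 at -1.45 and Mertk at -1.12, and an adjusted p of 0.558 with an estimated correlation. Arginase gene Arg1 rose by 2.56 and Ccl22 by 4.49, in a list of alternative activation of which 6 of 15 rose and 3 fell and for which the adjusted p was 0.207 with an estimated correlation.

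Among markers of other cells, 3 of 5 neutrophil genes rose and 0 fell (5 and 0 adjusted over the list alone), including the collagenase and gelatinase genes Mmp8 (1.22) and Mmp9 (0.52), with an adjusted p of 0.107 with an estimated correlation. Of 9 mesothelial genes 0 rose and 3 fell, and of 9 dendritic cell and monocyte genes 4 rose and 2 fell. In total 4109 of 13630 genes passed the threshold between SRBI knockdown and control, 1998 higher and 2111 lower, and 6477 genes (47.5%) had no overlap between groups where chance gives 10%.

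**Figure D3:**
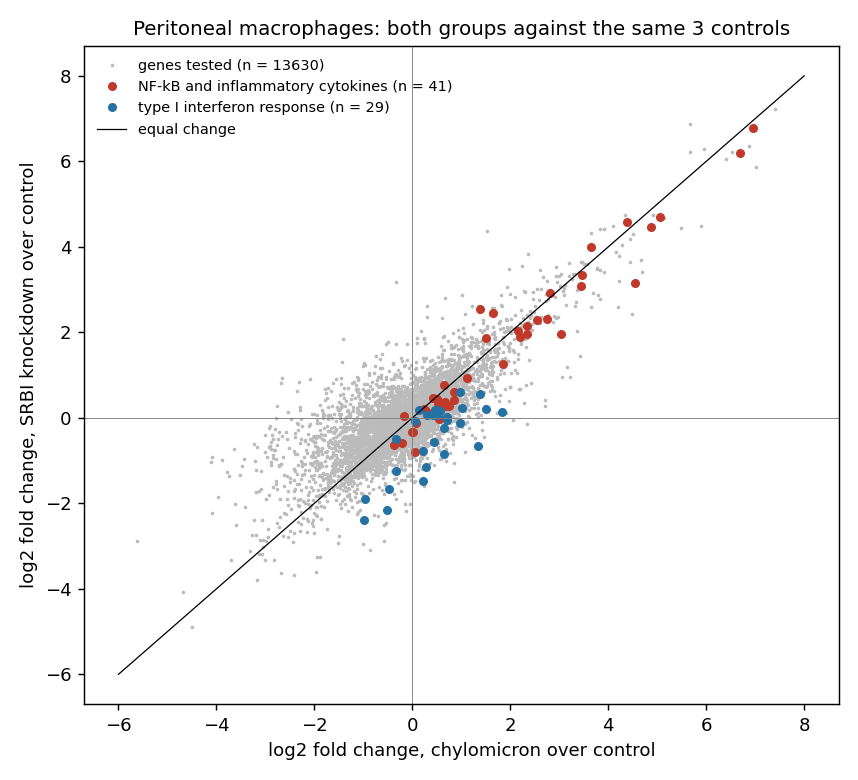
Log2 fold change over control of 13630 genes in chylomicron macrophages (horizontal axis) and SRBI knockdown macrophages (vertical axis), with 41 NF-kB and inflammatory cytokine genes and 29 type I interferon response genes in colour. By the direct test 5 of the inflammatory genes were higher and 21 lower in SRBI knockdown than in chylomicron libraries, and 23 interferon genes were lower.

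The changes against control in both macrophage groups overlapped. The same 1385 genes were higher and the same 1557 lower in both, where independent lists of these sizes would share 319 and 367, and 34 genes were called in opposite directions. Both comparisons used the same 3 control libraries, which alone makes fold changes alike. Across genes, which are not independent replicates, the fold changes had a correlation of 0.796, against a mean of 0.495 in 20 simulations of unchanged groups with shared controls. The covariance was 0.362 against 0.0459 in the simulations. Controls shared between the comparisons can thus account for at least part of the likeness, and 3 controls were too few to be divided between them. No simulated gene was called in both comparisons, but each gene was drawn independently and without a group effect. A shift common to many genes of the control libraries was not simulated. How much of the overlap goes beyond the shared controls therefore stays open.

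The fold changes of SRBI knockdown against chylomicron macrophages did not involve the controls, but the tests took their spread from all 9 macrophage libraries. With the 6 compared libraries alone 1199 genes passed in place of 1525. The chylomicron libraries were not a tight group. PMAC chylomicron replicate 3 correlated at 0.987, 0.990 and 0.989 with the SRBI knockdown libraries. With PMAC chylomicron replicates 1 and 2 it correlated at 0.973 and 0.976. On the first principal component it lay at 19.0, replicates 1 and 2 at 43.5 and 37.5, and the SRBI knockdown libraries at 13.8 to 17.5. Interferon-induced genes such as Ifi205 and Gbp5 were lower in SRBI knockdown, as were genes of other kinds such as Cst7 and Fabp3. Ifi205 averaged 140 ± 9.09 normalized counts (SD, n = 3) against 789 ± 62.3, a log2 fold change of -2.48 (adjusted p = 3.72e-08), Gbp5 fell by 1.71 on the log2 scale, Cst7, a cystatin of the endolysosome, fell by 1.92, and Fabp3 fell by 1.87. Higher in SRBI knockdown were Slco4a1 (1.76), the cholesterol 25-hydroxylase gene Ch25h (1.73), Stfa3 (1.52) and Mmp8 (1.39, adjusted p = 9.37e-09). Of 29 type I interferon response genes 0 rose and 23 fell (0 and 26 adjusted over the list alone), including Oasl1 (-1.70), Isg15 (-1.09) and Zbp1 (-0.81), and the call held with an estimated correlation (adjusted p = 0.0462). Of 29 type II interferon and antigen presentation genes 1 rose and 21 fell (1 and 22 adjusted over the list alone), including the major histocompatibility genes H2-Aa (-0.94), H2-K1 (-0.61) and H2-D1 (-0.50), with an adjusted p of 0.0624 with an estimated correlation.

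Fatty acid synthesis genes were higher in SRBI knockdown than in chylomicron macrophages. Of 15 members 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Scd2 at 1.16, Fads1 at 0.56 and Fasn at 0.44, and the call held with an estimated correlation (adjusted p = 0.0462). With empirical Bayes without a trend 2 of these rose and Fasn did not pass (adjusted p = 0.0550, over a range of 2.98e-05 to 0.0550). Of the 38 genes named in this comparison and past the threshold, 4 lost their call in at least 1 alternative. Of 41 NF-kB and inflammatory cytokine genes 5 rose and 21 fell (6 and 24 adjusted over the list alone). Il12b fell by 1.37, Ccl5 by 1.07 and Cd40 by 0.85, while Ccl2 rose from 8642 ± 421 to 19479 ± 2481 normalized counts, and the adjusted p was 0.299 with an estimated correlation. Of 21 chemokine and leukocyte recruitment genes 8 rose and 6 fell (9 and 6 adjusted over the list alone), with Ccl6 at 0.69 and Ccr1 at 0.43, and camera gave an adjusted p of 0.178. Of 23 unfolded protein response genes 0 rose and 13 fell (0 and 17 adjusted over the list alone), including Sdf2l1 (-0.55), Creld2 (-0.52), Hspa5 (-0.46) and Manf (-0.36), with an adjusted p of 0.0995 with an estimated correlation. Of 24 integrated stress response targets 0 rose and 6 fell (1 and 6 adjusted over the list alone), including Gdf15 (-1.53) and Asns (-1.10), with an adjusted p of 0.216 with an estimated correlation. In the list of ribosomal proteins 0 rose and 11 fell, and the number that fell ranged from 1 to 20 over the alternatives. For that list camera gave an adjusted p of 3.69e-12 at the preset correlation, and up to 0.00127 over the alternatives. A value with an estimated correlation is not given here for ribosomal proteins, so no change of that list is concluded. Without PMAC chylomicron replicates 1 and 2 together, 15 type I interferon, 5 unfolded protein response and 3 integrated stress response genes fell. With empirical Bayes without a trend, 8 inflammatory genes fell and 3 rose, and 15 type I interferon, 7 unfolded protein response and 3 integrated stress response genes fell.

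Markers of other cells moved in this comparison too. Of 8 mast cell and eosinophil genes 0 rose and 3 fell (0 and 6 adjusted over the list alone), including the mast cell carboxypeptidase gene Cpa3 (-1.41), with an adjusted p of 0.299 with an estimated correlation. Of 5 neutrophil genes 2 rose (Mmp8, and Mmp9 at 0.80) and 1 fell, and of 9 dendritic cell and monocyte genes 2 rose and 0 fell. In total 1525 of 13630 genes passed the threshold, 763 higher and 762 lower, and 3717 genes (27.3%) had no overlap between groups where chance gives 10%. Scarb1 was not lower in SRBI knockdown than in chylomicron macrophages, with a log2 fold change of 0.17 (adjusted p = 0.163, 95% interval 0.01 to 0.33). The count was 822 without PMAC SRBI knockdown replicate 1, 937 without PMAC SRBI knockdown replicate 2, 618 without PMAC chylomicron replicates 1 and 2 together, and 602 with empirical Bayes without a trend.

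**Figure D4:**
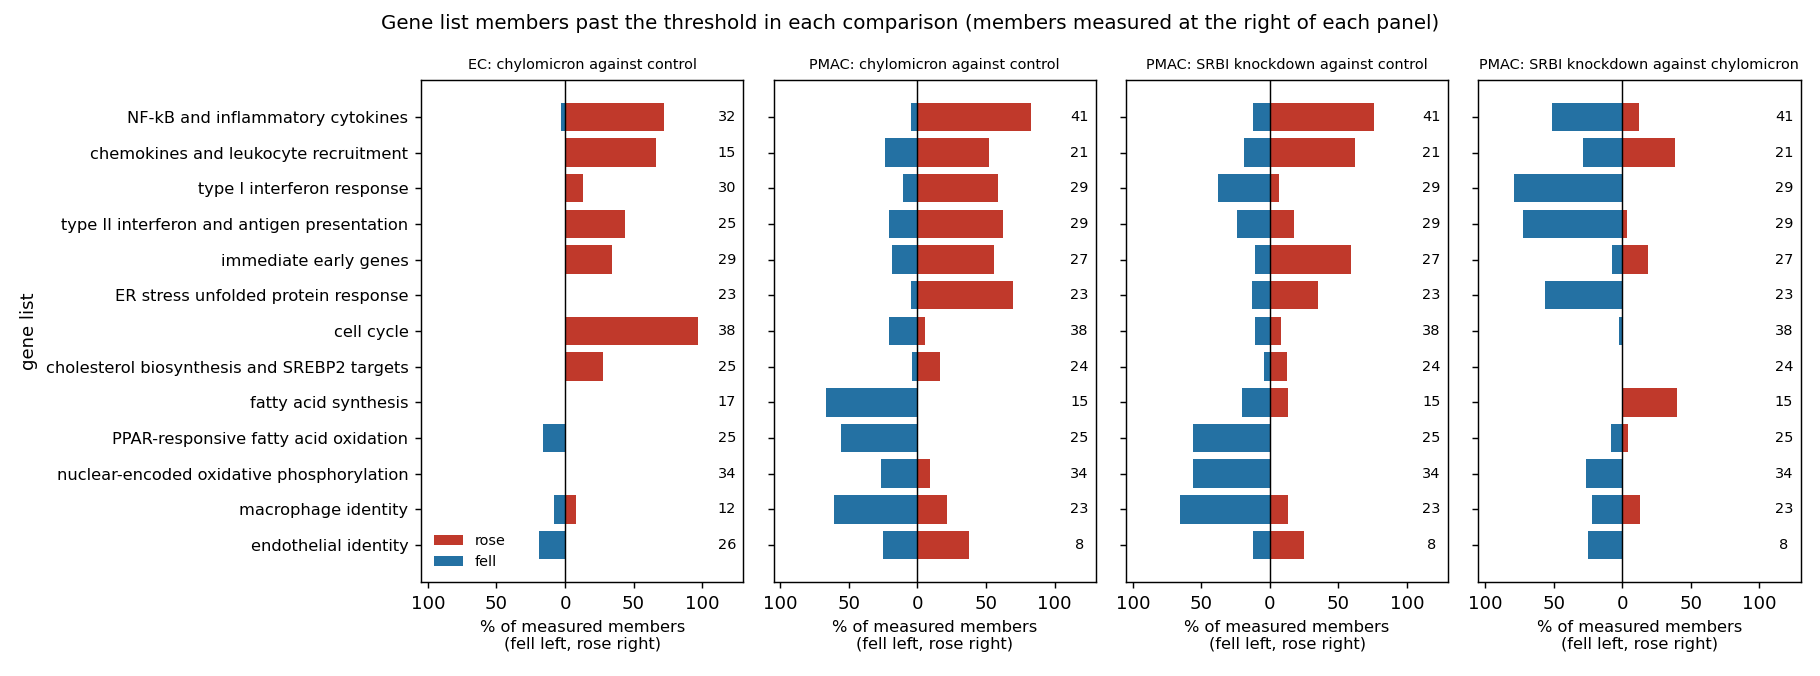
Percent of the measured members of 13 gene lists that fell (left) or rose (right) in each of the 4 mRNA comparisons, with the number measured at the right of each panel. NF-kB and inflammatory cytokine genes rose in 23 of 32 in endothelial cells and in 34 of 41 in chylomicron macrophages, and type I interferon response genes fell in 23 of 29 between SRBI knockdown and chylomicron macrophages.

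The medium of endothelial cells was dominated by a few miRNAs. miR-99a-5p averaged 205014 ± 31495 CPM (TMM-scaled counts, SD, n = 3) in control media and 207843 ± 33130 in chylomicron media, followed in both groups by miR-148a-3p and let-7i-5p. miR-21a-5p, miR-152-3p and miR-27a-3p merged with miR-27b-3p came next, in an order that differed between the groups. No miRNA separated chylomicron from control media at the threshold. By edgeR 0 of 431 passed, 31 had an unadjusted p under 0.05, and DESeq2 and voom also called 0. The log2 fold change of miR-99a-5p was 0.02 (95% interval -0.35 to 0.39) and that of miR-148a-3p was 0.31 (95% interval -0.08 to 0.69). The smallest p values were those of miR-219a-5p (log2 fold change 1.72, adjusted p = 0.617), miR-199a-3p merged with miR-199b-3p (-0.57), miR-29c-3p, miR-7a-5p (-0.59), miR-146b-5p (-0.48) and miR-3473b merged with miR-3473e (1.40). None of 14 lists had a member past the threshold. The miR-15 and miR-16 family was called lower by camera at the preset correlation (adjusted p = 0.0456), a call kept in 4 of 14 alternatives, and with an estimated correlation the lowest adjusted p of a list was 0.628. With no filter on low counts 4 were called, miR-3473b merged with miR-3473e, miR-29b-3p, let-7f-1-3p and miR-8095, the last 3 being named after their values were seen. Their mean counts were 581, 998, 19.9 and 11.2, so each had passed the filter of 5 and was not called in the main test. The calls thus came from a changed fit and not from added miRNAs. The highest count in a library was 97 for let-7f-1-3p and 53 for miR-8095. In the simulated run at this depth the test called 5.56% (1 of 18) of changes of 1 on the log2 scale and 60.0% (12 of 20) of those of 2, so most simulated changes of 1 were not called.

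In media labelled SRBI knockdown, a small set of miRNAs differed from control. miR-21a-5p, an abundant miRNA linked to inflammation, averaged 20240 ± 1181 CPM (SD, n = 3) against 64261 ± 6370 in control, a log2 fold change of -1.67 (adjusted p = 3.10e-05). miR-155-5p, which is induced in activated immune and endothelial cells, averaged 977 ± 273 against 135 ± 12.6, a log2 fold change of 2.85 (adjusted p = 8.53e-05). miR-151-3p rose by 1.56 on the log2 scale, miR-30d-5p by 1.62 and miR-30e-5p by 1.54, and miR-146b-5p fell by 1.07. These 6 kept their calls in every alternative, and the other 10 named miRNAs past the threshold lost theirs in at least 1. Among those 10, miR-30a-5p (1.99) did not pass without control replicate 1 (adjusted p = 0.0873) or 2 (adjusted p = 0.121), over a range of 1.20e-17 to 0.121. miR-224-5p (1.02) did not pass without control replicate 2 (adjusted p = 0.0618), over a range of 7.66e-08 to 0.0618. miR-16-5p (-0.94) did not pass without control replicate 2 (adjusted p = 0.0618) or SRBI knockdown replicate 1 (adjusted p = 0.0783), over a range of 6.45e-09 to 0.0783.

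**Figure D5:**
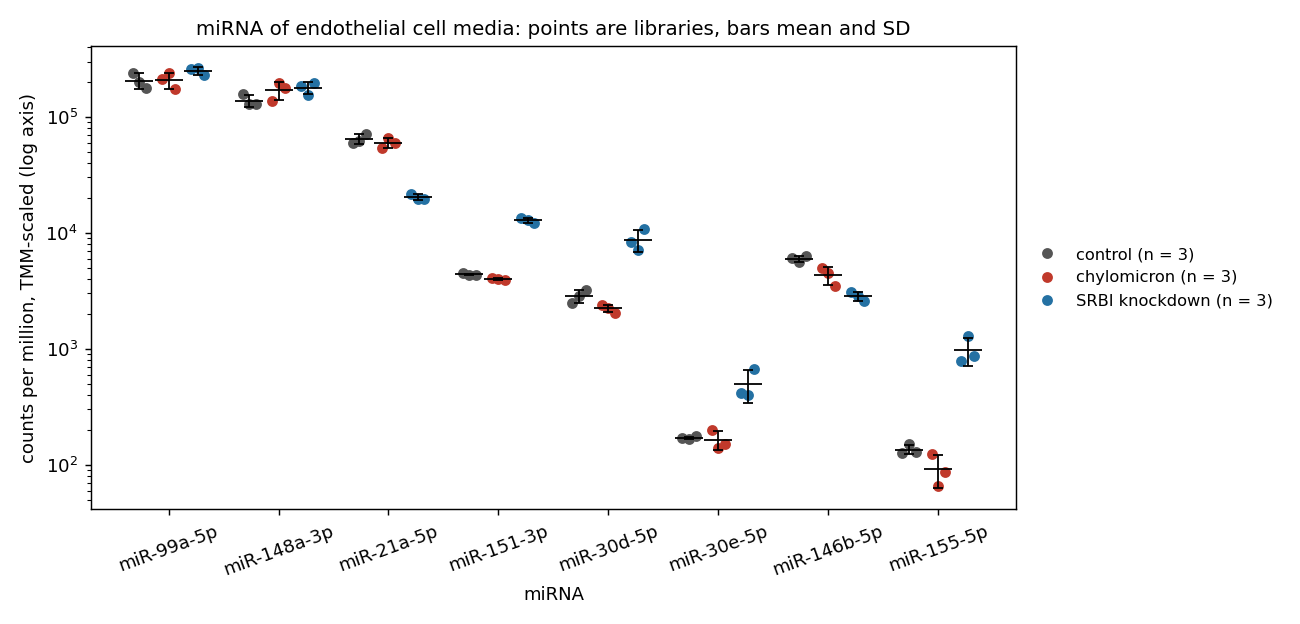
TMM-scaled CPM (log axis) of 8 miRNAs in the 9 libraries of endothelial cell media, with a point per library and bars for the mean and SD of each group of 3. miR-21a-5p and miR-146b-5p were lower and miR-151-3p, miR-30d-5p, miR-30e-5p and miR-155-5p higher in every SRBI knockdown library than in every control library.

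Of 16 measured members of the miR-30 and miR-29 families 3 rose and 0 fell against control (3 and 1 adjusted over the list alone), and camera gave an adjusted p of 0.0704. Of 13 members of the miR-15 and miR-16 family 0 rose and 2 fell (0 and 4 adjusted over the list alone), with an adjusted p of 0.363 with an estimated correlation. Of 26 inflammation-linked miRNAs 1 rose and 3 fell (1 and 3 adjusted over the list alone), and camera gave an adjusted p of 0.921. Of 11 miRNAs of myeloid and lymphoid cells 1 rose (miR-155-5p) and 0 fell, and of 9 of erythroid cells and platelets 0 rose and 1 fell (miR-16-5p). The erythroid miRNA miR-451a was at 944 CPM against 416 in control (log2 fold change 1.18, adjusted p = 0.0576). Over all miRNAs 18 of 431 passed, 8 higher and 10 lower. With library totals in place of TMM 14 passed, 9 higher and 5 lower. The count was 6 without control replicate 2, 9 without control replicate 3, 8 without SRBI knockdown replicate 1 and 48 without SRBI knockdown replicate 3. SRBI knockdown replicate 3 held 24282 CPM of miR-30a-5p, where the other SRBI knockdown libraries held 6938 and 9064.

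Against chylomicron media, a set of miRNAs differed in the same 3 SRBI knockdown libraries, so this comparison was not independent of that with control. miR-155-5p rose by 3.41 on the log2 scale, miR-30a-5p by 2.16, miR-30d-5p by 1.97, miR-151-3p by 1.68, and miR-30e-5p was also higher, while miR-21a-5p fell by 1.56 (adjusted p = 2.25e-05). miR-451a rose by 1.77 (adjusted p = 0.0146). Of 16 members of the miR-30 and miR-29 families 4 rose and 0 fell (4 and 0 adjusted over the list alone), 2 rose without chylomicron replicate 1, 2 or 3, and camera gave an adjusted p of 0.168. Of 32 endothelial-enriched miRNAs 2 rose and 0 fell (4 and 0 adjusted over the list alone), with an adjusted p of 0.168 by camera, and 6 rose and 2 fell without SRBI knockdown replicate 3. In total 12 of 431 passed, 11 higher and 1 lower, and with upper-quartile scaling 9 passed, 6 higher and 3 lower. The split was nearer even by DESeq2, with 25 higher and 20 lower, and without SRBI knockdown replicate 3, with 25 higher and 18 lower. The count was 5 without chylomicron replicate 2 or without chylomicron replicate 3, 7 without SRBI knockdown replicate 1 and 43 without SRBI knockdown replicate 3. miR-155-5p, miR-151-3p, miR-30d-5p, miR-30e-5p and miR-21a-5p kept their calls in every alternative. miR-30a-5p and miR-451a lost theirs without chylomicron replicate 2 (adjusted p = 0.112 for both) or 3 (0.0727 for both), and with the 6 compared libraries alone. miR-30a-5p also lost its call without chylomicron replicate 1 (adjusted p = 0.0510), and the ranges were 3.15e-20 to 0.112 for miR-30a-5p and 9.47e-13 to 0.112 for miR-451a.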

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

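The tests of macrophage RNA, of single libraries, of depth, of Scarb1, of leukocyte miRNAs and of scaling were chosen only after the results were seen. Chylomicron against control was compared in endothelial cells and in macrophages, although the labels leave open whether the macrophages received chylomicrons or endothelial vesicles. Of 82 genes taken for description in these comparisons and measured in both, 33 passed in both, 24 in the same direction and 9 in opposite directions. In 8 of the 9 every chylomicron library lay on one side of the controls in one cell type and on the other side in the other. The difference between the cell types was not tested, and the libraries came from separate tables. The endothelial log2 fold change minus the macrophage one was -5.03 for Il1a (-1.56 and 3.47), 2.60 for the receptor gene Tlr2 (2.43 and -0.16), 2.57 for the adhesion receptor gene Icam1 (2.20 and -0.37) and 2.12 for the thymidine kinase gene Tk1 (0.76 and -1.36). It was -1.99 for Id2 (-1.28 and 0.71), 1.83 for the LXR gene Nr1h3 (0.96 and -0.87), 1.52 for Rrm2 (0.91 and -0.61) and 1.27 for Cd82 (0.82 and -0.45). Endothelial Il1a and Tk1 and macrophage Nr1h3, Tlr2 and Rrm2 lay outside the naming rule and were named after their values were seen. Il1a in endothelial cells did not pass without EC control replicate 1 (adjusted p = 0.0837, over a range of 3.23e-04 to 0.108).

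In macrophages the calls of Tlr2 and Rrm2 lay close to the threshold, with log2 fold changes of -0.23 to -0.13 and -0.72 to -0.41 over the alternatives. Tlr2 did not pass without PMAC chylomicron replicate 1 (adjusted p = 0.0545) or 3 (0.0682) or without PMAC control replicate 1 (0.0515) or 2 (0.0641), over a range of 3.68e-04 to 0.0745. Rrm2 did not pass without PMAC chylomicron replicate 1 (adjusted p = 0.0550) or 2 (0.0818) or without PMAC control replicate 1 (0.0821), 2 (0.0573) or 3 (0.0924), over a range of 0.0238 to 0.311. Rrm2 also missed the threshold with no filter (0.0638), quantile normalization (0.0659) and sample weights (0.0711), and Tlr2 with empirical Bayes without a trend (0.0745).

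Inflammatory transcripts were higher in chylomicron-treated endothelial cells. Macrophages among the cells would bring their abundant transcripts along, but the 12 macrophage identity genes measured had a median log2 fold change of -0.37 where the 23 inflammatory genes that rose had a median of 1.40, and the 23 genes of the macrophage list summed to 0.206% of the macrophage control level with chylomicrons and 0.230% in controls. The chylomicron library that stood apart did not carry the pattern, since 24 inflammatory genes rose without it and 23 with it. A response of the endothelial cells to chylomicrons may be the source, as a hypothesis that was not itself tested. Anything else in the chylomicron preparation was not tested and stays open. A response of fibroblast-like cells present in both groups was not tested either. The matrix gene Fn1 took the most reads in EC control replicates 2 and 3, and Col3a1 did in EC chylomicron replicate 2.

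Type I interferon response genes were lower in SRBI knockdown than in chylomicron macrophages. Lower depth of the chylomicron libraries did not account for this, since 22 of the 29 genes fell after all libraries were thinned to equal reads and 23 before. With both chylomicron libraries that stood apart left out 15 fell, so those libraries were not the whole of it, although the remaining library was then assumed to vary like the other groups. Scarb1 transcript was not lower in the knockdown than in the chylomicron macrophages, with a log2 fold change of 0.17 (95% interval 0.01 to 0.33). Against control it was lower in both, at -0.26 in knockdown and -0.43 in chylomicron macrophages. The comparison with chylomicron macrophages therefore cannot tell whether the knockdown lowered Scarb1. An effect of the knockdown in other cells may be a source, as a hypothesis, but the labels do not state in which cells it was made. That and differences in handling between the groups were not tested.

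miR-155-5p was higher in media labelled SRBI knockdown. The 9 other myeloid and lymphoid miRNAs measured, leaving out the opposite strand miR-155-3p, had a median log2 fold change of 0.38 (SD 0.55, highest 0.97). That of miR-155-5p was 2.85, so these miRNAs did not rise alike. Activated immune cells induce miR-155-5p, so these values cannot tell whether RNA from myeloid or lymphoid cells was a source. Scaling of libraries dominated by a few miRNAs did not account for the higher miR-155-5p. Its lowest log2 fold change under 4 other scalings was 2.89. An effect of the knockdown on the endothelial cells may be a source, as a hypothesis. Other differences between the knockdown and control cultures were not tested.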

How the results depend on the processing

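Analyses with edgeR or DESeq2 on the recovered reads, without the libraries that stood apart, and with thinned reads, and every alternative for the overlap of the macrophage comparisons, were chosen only after the data were seen. Of the values of named genes and miRNAs past the threshold under an alternative, 4298 kept their side of it and direction and 99 did not pass. Among those not past it 310 stayed so, 25 passed and 4 reversed. The reversed ones were all in chylomicron against control media, where no call had been made. With upper-quartile scaling, which shifted the median by 0.20 on the log2 scale, let-7i-5p was at 0.0939 and miR-27a-3p merged with miR-27b-3p at 0.0364. miR-99a-5p was at -0.0662 without chylomicron replicate 2, over a range of -0.0681 (without control replicate 3) to 0.148 with a library left out. Upper-quartile scaling also shifted the median by -0.14 between SRBI knockdown and chylomicron media. The cause was not tested.

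The count of genes past the threshold in endothelial cells was 587 with empirical Bayes without a trend, 212 at an absolute log2 fold change of at least 1, and 744 to 1549 with a library left out, the lowest without EC control replicate 1 and the highest without EC chylomicron replicate 2. It was 803 without EC control replicate 2 and 933 without both EC chylomicron replicate 2 and EC control replicate 1. edgeR gave 1301 and DESeq2 1608 on the recovered reads. For chylomicron against control macrophages it was 970 at an absolute log2 fold change of at least 1 and 3663 to 4437 with a library left out, with 4489 by edgeR and 4698 by DESeq2. For SRBI knockdown against control it was 764 and 3262 to 3618, with 4238 by edgeR and 4466 by DESeq2. For SRBI knockdown against chylomicron macrophages it was 602 with empirical Bayes without a trend, 618 without both chylomicron libraries that stood apart, 122 at an absolute log2 fold change of at least 1, and 822 to 1798 with a library left out, 937 being without PMAC SRBI knockdown replicate 2. Fewer genes can pass at a larger required change or with fewer libraries by construction, and the cause of the drop without a trend was not tested. The number called in the same direction in both macrophage comparisons was 2942, 550 at an absolute log2 fold change of at least 1, and 2420 to 3057 with a library left out.

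For chylomicron against control media 4 were called with no filter and 0 with any library left out. For SRBI knockdown against control 50 were called by DESeq2, 46 with no filter, 33 at a mean count of at least 50, 10 at an absolute log2 fold change of at least 1, and 6 to 48 with a library left out. For SRBI knockdown against chylomicron 45 were called by DESeq2, 41 with no filter, 24 at a mean count of at least 50, 5 with the 6 compared libraries alone, and 5 to 43 with a library left out. Among the counts with a library left out, the highest were both without SRBI knockdown replicate 3. With a term for the replicate number 33 and 29 were called. Deviations from the group means correlated at -0.19 to 0.22 between libraries of equal number and at -0.24 to 0.22 between those of unequal number. Above 0.1 were 4 of 9 pairs of equal number and 3 of 18 of unequal number. So few pairs cannot show whether the numbers paired the samples. Other causes of these shifts were not tested. In the media libraries, at 750534 to 2786583 counts, 5.56% (1 of 18) of changes of 1 on the log2 scale were called in the simulated run at the measured depth.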

Other observations

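The count of genes shared by the endothelial and macrophage comparisons was chosen only after the data were seen, while the splits of the libraries were set before. Of 12461 genes tested in both cell types, 484 passed in both for chylomicron against control, although the labels leave open whether both cell types received the same treatment. Higher in both were 162, where independent lists would share 110, and lower in both were 115, where they would share 58.7. A further 157 were higher in endothelial cells and lower in macrophages, where independent lists would share 121, and 50 the reverse, where they would share 53.6.

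Each comparison was repeated over the 10 splits of its 6 libraries into groups of 3, the real one included. The smallest share possible was 1 of 10, so a share under 0.05 could not arise. Every other split put libraries of both groups on each side. Any difference between the groups, whatever its source, then widens the spread and tends to lower the count. A count of 0 in the other splits therefore lends no support to the calls. As many genes as the real 1317 in endothelial cells came from 1 split, the real one, and the highest other gave 0. The same held for the 4550, 4109 and 1525 genes of the macrophage comparisons and the 18 miRNAs of SRBI knockdown against control media, each with 1 split and 0 as the highest other. For chylomicron against control media, with 0 real calls, all 10 splits gave as many and the highest other gave 1. For SRBI knockdown against chylomicron media, with 12 real calls, 2 splits gave as many. The other gave 49 calls and set chylomicron replicate 1 with SRBI knockdown replicates 1 and 2 against chylomicron replicates 2 and 3 with SRBI knockdown replicate 3, which points to a structure of these samples beyond their groups.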
